A study of Homo sapiens with 96 samples.

How the data were processed

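Total RNA and ribosome-protected fragments (footprints, the mRNA pieces covered by a translating ribosome) were sequenced in U2-OS cells, a human osteosarcoma line that here carries a luciferase reporter driven by the Per2 promoter. Per the labels' protocols, cells were synchronised with 0.1 µM dexamethasone, a synthetic glucocorticoid that resets the cellular clock, and collected from 24.5 h after synchronisation every 2 h over 1 day, after cycloheximide at 100 µg/mL to hold ribosomes in place. The 96 libraries fall into 48 groups by treatment, assay and circadian time (CT00 to CT22), with 2 replicates each. Wild-type cells received no siRNA and were seeded at 2250000 cells per plate. Knockdown cells were seeded at 560000 cells per plate and received 120 pmol of a mix of 5 siRNAs (short RNAs that direct cleavage of a matching mRNA) against Bmal1, whose gene symbol in the files is ARNTL. The labels give no control siRNA, so the knockdown effect includes transfection, seeding density and everything else that differed between the treatments' series.

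Reads were aligned with STAR 2.3.0e to GRCh37 (hg19), counted per gene with HTSeq 0.5.4p1 and normalised with DESeq2, whose version is not given, per the submitters' processing notes. The strand setting of the counting is not stated, so genes that overlap an antisense gene, and families with near-identical members such as histones and ribosomal proteins, are uncertain wherever their values are given. The deposited values are a normalised signal: gene counts that the authors divided by 1 factor per library. In the 8 deposited tables, 100% of the values were whole multiples of a single step per library within 0.001 read, so whole reads were recovered from them. The value of 1 read was 0.368 to 2.82 deposited units in total RNA and 1.19 to 2.98 in footprints. Each table holds 19438 genes, of which 790 had no read in any library; 18668 symbols were matched to a RefSeq gene table as current symbols or unambiguous synonyms. Column names give only the time, so treatment, assay and replicate were taken from the table each column sits in. No genome or gene models of that build were at hand, so no coordinates, GC content or lengths were used.

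Recovered reads (in units of 1e+06 reads, M) totalled 13.6 to 20.1 M in 46 of the 48 total RNA libraries, and 2.66 and 2.56 M in the knockdown total RNA libraries of replicate 2 at CT14 and CT18. The 48 footprint libraries held 2.50 to 5.82 M reads. A count of 3 reads was taken as the floor, and floors cover counting error only, since reads carry no molecular identifiers. Replicates of a group differed more than counting error alone gives, with a chi-square per degree of freedom of 1.40 to 10.8 over 48 pairs. Nothing in the labels says that replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

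Tests assuming counts were chosen before the data were examined, as were the comparisons, the gene lists and the rule for naming genes. Because the deposited values were normalised, the main test became limma-trend (limma 3.58.1, R 4.3.3, with robust empirical Bayes) on log2 counts per M reads (CPM) plus a pseudocount of 0.25, with recovered reads scaled by TMM within each assay (edgeR 4.0.16) and genes kept by filterByExpr with a minimum count of 10. The planned edgeR quasi-likelihood test on recovered reads became an alternative. Genes were called at a Benjamini-Hochberg adjusted p of 0.05, and every adjusted p of a gene is from limma unless another tool is named. The pseudocount makes folds of weakly expressed genes smaller than they are.

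The knockdown effect was the mean over the 12 times of knockdown minus wild-type, fitted with 1 mean per treatment and time. Its effect on translational efficiency, the ratio of footprints to total RNA, was the difference of that contrast between assays. Rhythms were F tests of a cosine and a sine of 24 h, within each treatment and assay, with treatment interactions for a change of rhythm and assay interactions for efficiency. An amplitude is the distance from the fitted mean to the peak. A single day cannot separate a rhythm from a drift, and a steady trend fits a cosine peaking near CT 5 or CT 17, so a linear drift was added as an alternative. Footprints and total RNA of a time and replicate came from the same lysate by number only.

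Of 25 gene lists, those with at least 5 tested members were tested against other genes with limma's camera (preset correlation 0.01, and again with an estimated correlation) for the knockdown and with a two-sided Fisher exact test for rhythms, adjusted over lists. The Fisher test takes genes as independent, so its p-values do not cover correlation among the members of a list. The genes named were fixed by rule. For the knockdown they were the 10 largest rises and 10 largest falls past the threshold with a mean log2 CPM of at least 1 and the same sign at all 12 times. For rhythms they were the 12 largest amplitudes past the threshold. To these were added the clock genes and up to 4 members, by adjusted p, of each list past the threshold. Single values were tested with 100000 two-sided permutations, whose smallest p is 1e-05. Genes are not independent replicates, so footprint and RNA amplitudes were compared without a test across genes.

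Replicate numbers were taken to pair samples where every pair of same-numbered libraries deviated from the group means with a correlation over 0.1, decided before calls were compared. This held over the times of wild-type total RNA (66 pairs, 0.41 to 0.70, median 0.57) and between total RNA and footprints in wild-type cells (12 pairs, 0.21 to 0.42, median 0.32), so the pairing comes from the data and not from the labels. Values with a replicate block are given beside results on these libraries where the block moved a count of genes or the call of a list.

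Alternatives covered median-ratio scaling (DESeq2 1.42.0), the deposited scaling, a joint scaling of both assays, no filter and a stricter filter, pseudocounts of 0.1 and 1, a threshold of 0.01, fold and amplitude thresholds, edgeR, DESeq2, limma voom, library weights, replicate and lysate blocks, a factor of the 12 times, a period of 12 h, and leaving out each replicate, time, library and the 2 shallow libraries. Tables and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. On data simulated from the real means and depths with known changes of 0.25, 0.5 and 1 log2 units, the main test recovered 71.6%, 100% and 100% of changed genes for the knockdown effect on total RNA, 68.7%, 92.5% and 100% for footprints, and 43.3%, 92.5% and 98.5% for efficiency. It recovered rhythms of those amplitudes at 76.1%, 100% and 98.5% in wild-type total RNA, 52.2%, 94.0% and 100% in wild-type footprints, and 26.9%, 80.6% and 100% for wild-type efficiency. Unchanged genes made up 2.1% to 6.3% of calls over the 11 tests. The simulated libraries were independent and had no drift or deviations shared by a series. These shares therefore do not cover false calls from either in the real data. In the list tests, 1 of 1 changed list was found and 0 of 20 unchanged lists were called. Simulated genes varied independently, so this could not show calls of lists caused by correlation among their members.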

Results

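The data cover 1 circadian day of U2-OS osteosarcoma cells, with and without siRNA against the clock gene Bmal1 (ARNTL). Each treatment was sampled at 12 times by total RNA sequencing, which measures mRNA abundance, and by ribosome profiling, which counts mRNA fragments held inside ribosomes. With 2 replicates, each treatment and assay has 24 libraries. Total RNA libraries held a median of 16.3 M reads and footprint libraries a median of 3.67 M (M, 1e+06 reads). A read was seen for 14132 to 15800 genes per total RNA library and 12851 to 14074 per footprint library. The design asks which genes depend on BMAL1, which are rhythmic in abundance or in ribosome occupancy, and whether translation adds rhythms of its own.

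ARNTL, the target, encodes the activator that pairs with CLOCK to drive E-box genes. Its total RNA averaged 32.5 ± 11.5 CPM (SD, n = 24) in wild-type libraries and 4.84 ± 0.710 CPM (n = 24) in knockdown libraries, or 14.9% of wild-type. Each knockdown library (3.36 to 6.49 CPM, 9 to 105 reads) lay under each wild-type library (14.3 to 47.9 CPM, 236 to 805 reads). In footprints ARNTL averaged 18.7 ± 7.31 CPM against 0.658 ± 0.425 CPM, 3.5% of wild-type, with 26 to 161 reads against 0 to 6. The target thus separated the treatments in all 96 libraries as labelled.

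NR1D2, a nuclear receptor (REV-ERB beta) that represses clock genes and is itself driven by BMAL1, fell by 2.85 ± 0.03 (log2 ± SE, adjusted p = 1.77e-36) in total RNA, from 163.5 to 21.98 CPM. ARNTL fell by 2.60 ± 0.05 (adjusted p = 7.68e-29). The repressor CRY2 rose by 1.19 ± 0.03 (adjusted p = 7.03e-25) and PER2 by 0.94 ± 0.05 (adjusted p = 5.52e-18), both at 12 of 12 times. DBP, a classic E-box output, fell by 1.08 ± 0.06 (adjusted p = 2.85e-17) and PER3 by 0.84 ± 0.04 at 11 of 12 times. BHLHE40, an E-box repressor, rose by 1.18 ± 0.05, while its relative BHLHE41 fell by 0.75 ± 0.15. WEE1, a mitotic kinase under clock control, fell by 0.54 ± 0.02, and RORA fell by 0.28 ± 0.05. Smaller rises were seen for NPAS2 (0.60 ± 0.09), RORB (0.37 ± 0.09), NFIL3 (0.24 ± 0.04), CRY1 (0.20 ± 0.02, adjusted p = 3.21e-09, 9 of 12 times) and ARNTL2 (0.12 ± 0.03). NR1D1 fell by 0.72 ± 0.14 (adjusted p = 2.66e-05), but at 1.58 and 0.935 CPM its total RNA is low, and it overlaps THRA on the other strand, so its value is uncertain. CLOCK (-0.02 ± 0.02, adjusted p = 0.317), TEF (adjusted p = 0.68), PER1 (adjusted p = 0.683) and HLF (adjusted p = 0.0858) were not past the threshold.

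In total RNA, 10778 of 13188 tested genes were past the threshold in limma, 5519 higher and 5259 lower in knockdown cells. Of these, 584 were at least 2-fold higher and 342 at least 2-fold lower. The fit takes libraries as independent, although wild-type total RNA libraries of a series share deviations (66 pairs, 0.41 to 0.70). Treatment labels exchanged within each time gave up to 5745 genes, and whole series exchanged gave at most 98. The SEs and p-values therefore do not cover the spread between series. RPF2, a ribosome assembly factor, fell from 34.6 to 3.27 CPM (log2 -3.33 ± 0.05, adjusted p = 2.31e-32). The troponins TNNT2 (-3.45 ± 0.08) and TNNC1 (-3.22 ± 0.10), the purine enzyme GMPR (-3.22 ± 0.10), the Ras effector RASSF2 (-3.17 ± 0.06), the transporter ABCB5 (-2.98 ± 0.13), the sodium channel SCNN1A (-2.77 ± 0.11) and C9orf84 (-2.74 ± 0.06) also fell. The largest named rises were in PRR9 (5.53 ± 0.09, adjusted p = 1.4e-31), the acetylcholine receptor CHRNA9 (4.99 ± 0.10), the secreted proteoglycan ESM1 (4.91 ± 0.20) and the survival factor BCL2A1 (4.70 ± 0.14). PRR9 had 0.0497 CPM in wild-type cells, so its fold rests on few reads. PTPN22, HTN1, SYP, DIO2, the cytokine IL1A and SPOCD1 rose by 3.85, 3.74, 3.74, 3.72, 3.66 and 3.62.

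Genes of DNA replication were lower in knockdown total RNA. The helicase subunit MCM3 fell by 1.21 ± 0.03 and ribonucleotide reductase RRM2 by 1.00 ± 0.02. CCNA2, the cyclin of S and G2 phase, fell by 1.12 ± 0.03 (adjusted p = 5.38e-25), and the mitotic genes NUSAP1, CENPF and KIF11 fell by 1.09, 1.06 and 1.00. The p53 target FDXR rose from 132.5 to 369.2 CPM (1.47 ± 0.02, adjusted p = 2.11e-31), with the death receptor TNFRSF10B (1.47 ± 0.03), BBC3 (1.13 ± 0.03) and SESN1 (1.12 ± 0.02). As lists, 25 of 26 S phase genes fell (median -0.82, camera adjusted p = 4.83e-13, or adjusted p = 0.0729 with an estimated correlation). All 29 G2 and M phase genes fell (median -0.80, adjusted p = 2.51e-12, or 0.349 with an estimated correlation), as did 12 of 12 histones (median -1.06, adjusted p = 5.53e-08, or 0.349). Of 19 p53 targets 18 rose and 1 fell (median 1.13, adjusted p = 1.6e-08, or 0.0729). These medians kept their sign under each of the 3 scalings. The median of all genes lay between 0 and 0.01 under them, so no sign could change and this adds no evidence. Histone values are uncertain because of near-identical members.

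Further list shifts in total RNA passed with the preset correlation, and none of them did with an estimated one. Respiratory chain subunits such as NDUFA10 (0.39 ± 0.02) and NDUFB8 (0.42 ± 0.02) were mostly higher (53 up, 6 down of 76, median 0.11, adjusted p = 0.00164, or 0.664 with an estimated correlation). Cytosolic ribosomal proteins such as RPS20 (0.27 ± 0.02) were too (53 up, 11 down of 78, adjusted p = 0.00558, or 0.75), but this call ended without replicate 2 (adjusted p = 0.324). Mitochondrial ribosomal proteins had 44 up and 14 down of 71 (adjusted p = 0.016, or 0.664), although MRPS10 fell by 1.09 ± 0.02. Targets of the amino acid stress factor ATF4 had 6 up and 18 down of 28 (median -0.22, adjusted p = 0.0299, or 0.633), with the serine synthesis gene PHGDH down by 1.33 (log2 -1.33 ± 0.04) and SESN2 up by 1.32. Extracellular matrix and osteoblast genes had 12 up and 3 down of 19 (median 0.80, adjusted p = 0.0299, or 0.349; 0.0565 without the 2 shallow libraries), led by COL6A1 (1.11 ± 0.03) and TNC (2.08 ± 0.07), with the collagen chaperone SERPINH1 down (-0.71 ± 0.02). Adjusted over the list alone, the counts were 25 S phase, 29 G2 and M phase, 19 p53, 12 histone, 59 respiratory, 64 cytosolic ribosomal, 58 mitochondrial ribosomal, 24 ATF4 and 15 matrix genes.

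Other lists were not past the threshold in total RNA. They were hypoxia and glycolysis (3 up, 16 down of 26, adjusted p = 0.107), endoplasmic reticulum chaperones (3 up, 10 down of 18, 0.126), other TOP mRNAs (12 up, 3 down of 17, 0.145) and clock kinases and ligases (1 up, 5 down of 9, 0.234). Glucocorticoid-induced genes had 4 up and 7 down of 14 (0.289), neuronal markers 2 up and 3 down of 6 (0.679), and cholesterol genes 13 up and 6 down of 23 (0.679). Clock repressors had 6 up and 7 down of 16 (0.729). That name is short for a list of clock repressors and E-box output. It also holds genes such as DBP, TEF, RORA and WEE1, so not all its members are repressors. Interferon-stimulated genes had 12 up and 7 down of 25 (0.729, with a median of 0.03 and a mean of -0.02), proteasome subunits 14 up and 10 down of 31 (0.748), heat shock genes 6 up and 5 down of 13 (0.833) and siRNA machinery 3 up and 3 down of 8 (0.833). Core clock activators (4 genes: ARNTL, ARNTL2, CLOCK, NPAS2), epithelial markers (CDH1, CLDN4, EPCAM, KRT14) and blood markers (CD68) had too few tested members. None of the 13 mitochondrial DNA-encoded mRNAs listed is in the files.

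**Figure D1:**
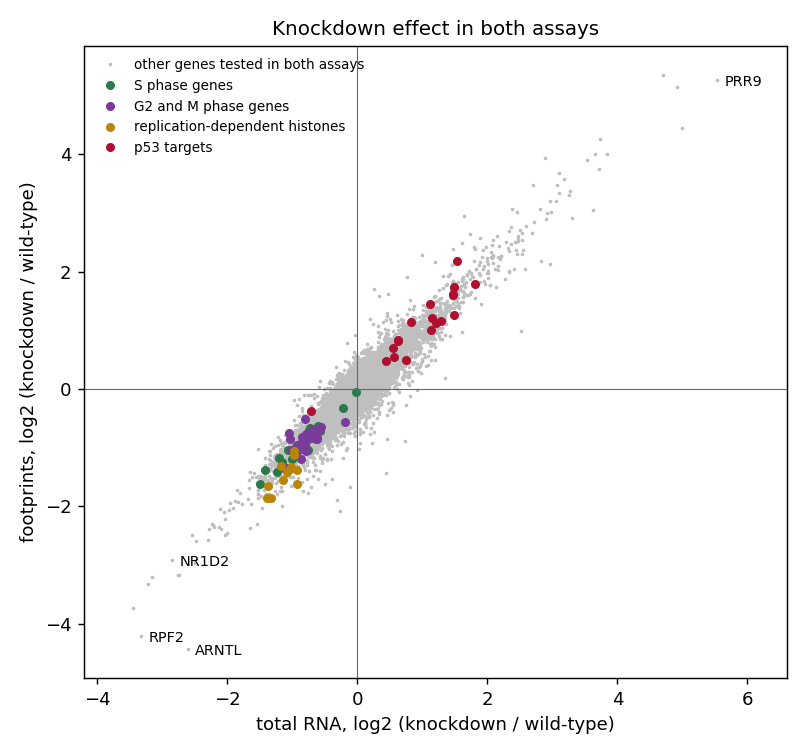
Each point is a gene, with the knockdown effect on total RNA (log2, x axis) against that on footprints (log2, y axis); colours mark S phase genes, G2 and M phase genes, histones and p53 targets. ARNTL, NR1D2 and RPF2 lie low on both axes and PRR9 high, S phase genes sit at a median of -0.82 and p53 targets at a median of 1.13 in total RNA, and the correlation across 11149 genes, which are not independent replicates, is 0.938.

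In footprints, NR1D2 fell by 2.92 ± 0.06 (adjusted p = 2.02e-35), ARNTL by 4.44 ± 0.17 (adjusted p = 3.88e-25) and RPF2 by 4.22 ± 0.15. NR1D1 (uncertain in footprints too) fell from 20.9 to 5.83 CPM (log2 -1.67 ± 0.09), DBP fell by 1.48 ± 0.10, PER3 by 1.30 ± 0.07, BHLHE41 by 0.96 ± 0.17, WEE1 by 0.50 ± 0.04 and PER1 by 0.23 ± 0.04. CRY2 rose by 1.59 ± 0.06, BHLHE40 by 1.09 ± 0.05, PER2 by 1.06 ± 0.09, NFIL3 by 0.27 ± 0.05 and ARNTL2 by 0.19 ± 0.08 (adjusted p = 0.0364). NPAS2 passed at 0.22 ± 0.09 (adjusted p = 0.0299), but was -0.01 without replicate 1 (adjusted p = 0.946) and 0.45 without replicate 2. CRY1 (0.01 ± 0.04, adjusted p = 0.841), CLOCK (adjusted p = 0.347), TEF (adjusted p = 0.194) and RORA (adjusted p = 0.324) were not past the threshold. Of 11189 genes, 8444 were past it, 4183 higher and 4261 lower, with 442 at least 2-fold higher and 382 at least 2-fold lower. With the deposited scaling 8517 were, and the share of higher calls was 61.4% against 49.5%. This fit also takes libraries as independent. Treatment labels exchanged within each time gave up to 3178 genes, and whole series exchanged gave at most 4. TNNT2 (-3.74 ± 0.21), TNNC1 (-3.32 ± 0.10), RASSF2 (-3.20 ± 0.14), C9orf84 (-3.17 ± 0.13), SCNN1A (-3.16 ± 0.17), the folate receptor FOLR1 (-2.97 ± 0.14) and FAM65B (-2.59 ± 0.15) fell. BCL2A1 (5.36 ± 0.20), PRR9 (5.26 ± 0.16), ESM1 (5.15 ± 0.22), CHRNA9 (4.45 ± 0.20), SYP (4.27 ± 0.15), PTPN22 (4.01 ± 0.21), the integrin ITGAX (3.94 ± 0.17), the protease MMP3 (3.91 ± 0.18) and DIO2 (3.75 ± 0.18) rose. In wild-type footprints BCL2A1, PRR9, ESM1, CHRNA9, PTPN22 and DIO2 averaged 0.06 to 0.38 CPM. Their folds rest on few reads and depend on the pseudocount. ESM1 also varied widely in knockdown footprints (26.3 ± 27.7 CPM, SD). Of genes past the threshold in total RNA and in footprints, 7552 were shared (7001.4 by independence), 7247 in the same direction.

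Among lists in footprints, S phase genes fell (25 of 26, median -0.96, camera adjusted p = 2.1e-15, which holds at 0.0136 with an estimated correlation), with MCM6 at -1.39 ± 0.04 and RRM2 at -1.17 ± 0.03. The p53 targets rose (18 of 19, 1 down, median 1.14, adjusted p = 1.41e-10, which holds at 0.00372), among them MDM2 at 1.14 ± 0.04 and RRM2B at 1.21 ± 0.04. G2 and M phase genes (29 of 29 lower, median -0.85, adjusted p = 1.42e-14, or 0.212 with an estimated correlation) included CCNA2 at -1.37 and CDC25B at -1.20. Histones fell in 12 of 12 (median -1.40, adjusted p = 4.09e-11, or 0.173). ATF4 targets had 6 up and 21 down of 27 (median -0.46, adjusted p = 0.0076, or 0.212), and matrix genes 12 up and 6 down of 20 (median 0.47, adjusted p = 0.0284, or 0.583; 0.0703 with the deposited scaling). The other 14 tested lists were not past the threshold, the lowest adjusted p being 0.143.

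SPTAN1, a spectrin of the membrane skeleton, led the rises in translational efficiency (1.46 ± 0.06, adjusted p = 3.98e-29), with footprints up from 46.6 to 153.5 CPM and total RNA at 83.5 and 99.7 CPM. ARNTL fell in efficiency by 1.84 ± 0.18 (adjusted p = 3.47e-12). It is the siRNA target, and its knockdown footprints held 0 to 6 reads per library, so this value is uncertain. PER3 (-0.46 ± 0.08), DBP (-0.40 ± 0.12), NPAS2 (-0.37 ± 0.13; adjusted p = 0.0747 without the 2 shallow libraries), PER1 (-0.25 ± 0.07) and CRY1 (-0.19 ± 0.05) fell and CRY2 rose (0.39 ± 0.07), while NR1D2 (-0.08 ± 0.06, adjusted p = 0.365) and PER2 (adjusted p = 0.423) were not past the threshold. NR1D1 (-0.96 ± 0.18) is uncertain. The esterase CES2 (1.29 ± 0.10), SHANK1 (1.26 ± 0.12), the inflammasome sensor NLRP1 (1.16 ± 0.11), NFKBIZ (1.14 ± 0.14), PCED1A (1.00 ± 0.12), CACNA1G (0.96 ± 0.14), ADAMTSL1 (0.96 ± 0.09) and GIGYF1 (0.94 ± 0.06) rose. SRRM3 (-1.87 ± 0.19), the transcription factor ZFHX3 (-1.81 ± 0.09), the metallothionein MT1E (-1.61 ± 0.16), C7orf10 (-1.53 ± 0.09), TMOD1 (-1.17 ± 0.13), IBTK (-1.14 ± 0.06) and the ubiquitin enzyme UBE2S (-1.13 ± 0.12) fell; MT1E and UQCRHL (-1.15 ± 0.06) have close paralogs and are uncertain. Of 11149 genes, 3465 were past the threshold, 1460 higher and 2005 lower, with 7 and 15 at least 2-fold. With series means, 2 against 2, 878 were. The share of higher calls was 42.1%, against 50.1% with median-ratio scaling, 54.0% with joint scaling and 80.4% with the deposited scaling (4621 calls), which moved the median of all genes from -0.01 to 0.09.

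RPL38 fell in efficiency by 0.79 ± 0.05 (adjusted p = 4.05e-22), and RPS12, RPS24 and RPS23 fell by 0.72, 0.69 and 0.50, values that are uncertain because the family has near-identical members. Cytosolic ribosomal proteins as a list had 4 up and 34 down of 66, 39 adjusted over the list alone (median -0.15, camera adjusted p = 6.08e-11, or 0.459 with an estimated correlation); the call ended without replicate 2 (adjusted p = 0.967), and with the deposited scaling 9 rose and 25 fell (median -0.05). Histones had 10 of 12 down, 11 over the list alone (median -0.33, adjusted p = 5.08e-09, or 0.459), with HIST2H2BE at -0.70 ± 0.07. Respiratory chain subunits such as COX7B (-0.45 ± 0.05) had 4 up and 37 down of 74, 43 over the list alone (adjusted p = 8.52e-06, or 0.459), but 12 up and 13 down with the deposited scaling. Mitochondrial ribosomal proteins such as MRPL42 (-0.34 ± 0.06) had 3 up and 28 down of 71, 33 over the list alone (adjusted p = 0.000856, or 0.459), but 16 up and 12 down with the deposited scaling, where the call ended (adjusted p = 0.0861). Of 19 p53 targets 9 were up and 2 down in efficiency (11 over the list alone, adjusted p = 0.0316, or 0.47), with SESN1 and CCNG1 at 0.33 and MDM2 at 0.32 (SE 0.05). That call ended without replicate 2 (adjusted p = 0.127) and without the 2 shallow libraries (0.0519). G2 and M phase genes and S phase genes both had an adjusted p of 0.061, and the lowest adjusted p among the remaining lists was 0.119.

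In wild-type total RNA, ARNTL was rhythmic with an amplitude of 0.75 ± 0.04 (log2 ± SE, adjusted p = 2.69e-11), a peak at CT 20 and a peak-to-trough fold of 2.82. NR1D2 peaked at CT 4.3 (0.50 ± 0.03, adjusted p = 8.01e-10), PER2 at CT 9.2 (0.77 ± 0.08, adjusted p = 5.65e-06) and CRY1 at CT 11.8 (0.27 ± 0.03, adjusted p = 8.4e-07). CRY2 (0.40 ± 0.05) peaked at CT 9, PER3 (0.56 ± 0.07) at CT 10.4, TEF (0.65 ± 0.09) at CT 7.3, PER1 (0.19 ± 0.03) at CT 6.2 and the repressor NFIL3 (0.26 ± 0.04) at CT 16.3. RORA, BHLHE41, WEE1, ARNTL2 and NPAS2 passed with amplitudes of 0.28, 0.76, 0.07, 0.12 and 0.30. NR1D1 (0.66 ± 0.10, CT 1.3) passed at low abundance. DBP (adjusted p = 0.295), CLOCK (0.491), BHLHE40 (0.953) and RORB (0.0866) were not past the threshold. With a linear drift in the model, ARNTL (adjusted p = 9.36e-12), NR1D2 (9.36e-12), PER2 (1.08e-10), PER3 (9.26e-10), CRY1 (2.67e-07), CRY2 (1.28e-07), TEF (1.31e-06) and NR1D1 (0.00122) stayed past the threshold and DBP passed it (0.00207). PER1, NFIL3, RORA, BHLHE41 and WEE1 lost their calls with the drift.

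**Figure D2:**
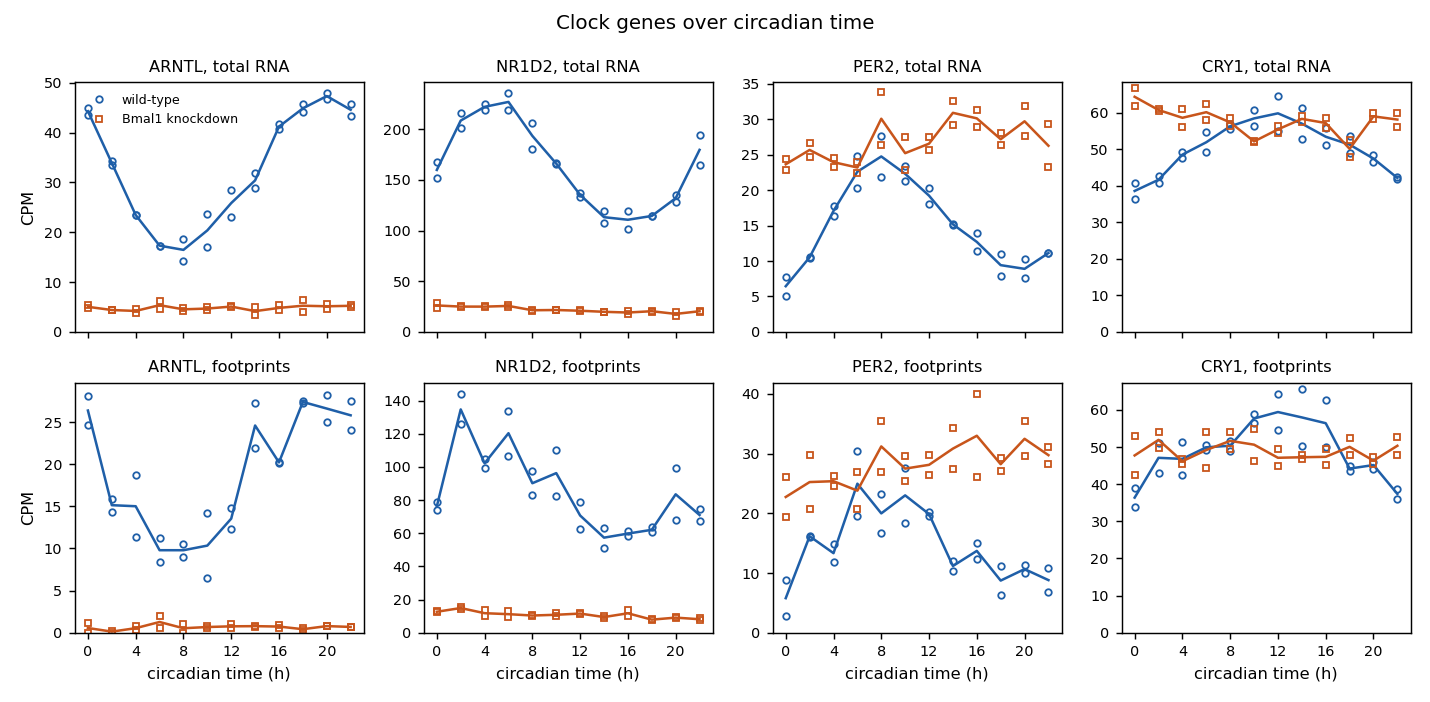
Expression (CPM, y axis) of ARNTL, NR1D2, PER2 and CRY1 over circadian time (h, x axis) in total RNA (top) and footprints (bottom); blue circles are wild-type and orange squares knockdown replicates, and lines join the mean of 2. Wild-type ARNTL peaks at CT 20 in total RNA with a 2.82-fold peak-to-trough change, and knockdown ARNTL stays between 3.36 and 6.49 CPM there.

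In all, 2855 of 12682 genes were past the threshold in wild-type total RNA, and 4830 with the replicate block, since replicate numbers pair these libraries. With a linear drift 25 were past it, a term that over a single day shares much of its fit with a wave. The selenium carrier SEPP1 (1.75 ± 0.28, CT 16.4), the dopamine receptor DRD1 (1.20 ± 0.26, CT 16.3), the chemokine CXCL14 (1.11 ± 0.19, CT 16.9), the growth factor PDGFB (1.03 ± 0.23, CT 16), FOXS1 (1.02 ± 0.24, CT 16.1) and BMF (1.02 ± 0.21, CT 16.1) had the largest amplitudes. RASAL1, C6orf99, ZBTB16 and PTP4A3 had amplitudes of 0.80, 0.79, 0.78 and 0.76. Leaving out CT02 lowered the count to 1791 and leaving out replicate 2 to 1619. Past the threshold were 24 of 29 G2 and M phase genes (6.53 expected, 27 adjusted over the list alone, Fisher's exact adjusted p = 1.99e-10, mean peak CT 5), among them AURKA (0.24 ± 0.04) and KIF23 (0.16 ± 0.02). So were 24 of 31 proteasome subunits (28 over the list alone, adjusted p = 1.36e-09), with PSMD2 at 0.26 ± 0.05, and 12 of 15 clock repressors (13 over the list alone, adjusted p = 2.65e-05). Heat shock genes had 10 of 13 (11 over the list alone, adjusted p = 0.00025), with HSPA1A at 0.16 ± 0.03, and glucocorticoid-induced genes 8 of 14 (8 over the list alone, adjusted p = 0.022), with FKBP5 at 0.14 ± 0.02. With a drift only the list of clock repressors and E-box output stayed past it (8 genes, TEF and DBP among them, adjusted p = 8.75e-18). G2 and M phase genes did too with a drift and the replicate block (5 genes, 0.000129). With the block, other TOP mRNAs (15 of 17, adjusted p = 0.00015), cytosolic ribosomal proteins (51 of 78, 1.11e-05) and matrix genes (13 of 19, 0.0224) passed, histones held fewer than expected (0 of 12 in limma, 1 at an unadjusted p under 0.05 and 1 in edgeR, 0.0174), and glucocorticoid-induced genes did not pass (9 of 14, 0.126, or 0.944 without replicate 2). The histone list mean peaked apart in the wild-type series, at CT 18 (amplitude 0.08) and CT 1.5 (0.155). Without replicate 1 histones instead held more rhythmic genes than expected.

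In wild-type footprints ARNTL (0.77 ± 0.08, adjusted p = 4.52e-06) peaked at CT 19.7, PER2 (0.74 ± 0.13, adjusted p = 0.00306) at CT 9, NR1D2 (0.47 ± 0.06, adjusted p = 0.000221) at CT 4.4, PER3 (0.58 ± 0.08) at CT 10.2 and CRY1 (0.29 ± 0.05) at CT 11.5. NR1D1 (0.74 ± 0.10, CT 0.6, uncertain), CRY2 (0.46 ± 0.08), TEF (0.52 ± 0.10), NFIL3 (0.29 ± 0.05), NPAS2 (0.41 ± 0.09) and PER1 (0.17 ± 0.04) passed. BHLHE41 (adjusted p = 0.0901), DBP (0.449), CLOCK (0.448) and WEE1 (0.655) did not. CXCL14 (1.17 ± 0.24, CT 16.7), the actin bundler LCP1 (0.95 ± 0.17, CT 4.5), ADAM22 (0.85 ± 0.20), IGFBP5 (0.85 ± 0.12), SLCO2A1 (0.81 ± 0.14) and SSPN (0.80 ± 0.16) had the largest amplitudes. In all, 753 of 10736 genes passed, and 7 with a linear drift. Leaving out CT04, CT18 or CT20 lowered the count to 293, 308 or 377, leaving out the replicate 1 library of CT18 to 474, and leaving out replicate 1 or 2 to 462 or 140.

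Proteasome subunits (19 of 30 past the threshold in wild-type footprints, 27 adjusted over the list alone, Fisher's exact adjusted p = 4.99e-14) included PSMD2 at 0.23 ± 0.04. Clock repressors had 9 of 14 (11 over the list alone, adjusted p = 5.7e-07; 5 with a drift), cytosolic ribosomal proteins 17 of 66 (35 over the list alone, 1.01e-05), and G2 and M phase genes 11 of 29 (16 over the list alone, 1.01e-05) with PLK1 at 0.27 ± 0.04. Matrix genes had 7 of 20 (8 over the list alone, 0.000943), with COL3A1 at 0.63 ± 0.13 and RUNX2 at 0.41 ± 0.08, and S phase genes 8 of 26 (8 over the list alone, 0.000943), with TYMS at 0.13 ± 0.02. Mitochondrial ribosomal proteins had 0 of 71 in limma (16 at an unadjusted p under 0.05, and 1 past the threshold in edgeR), fewer than the 4.98 expected (adjusted p = 0.0263; 0.138 without replicate 1 and 1 without replicate 2). The mean of these 71 genes still fitted a small wave (0.067 ± 0.012, permutation adjusted p = 0.00154 over 120 fits). Its peak at CT 5.1 is one that a steady trend also gives. Without replicate 2 the calls of cytosolic ribosomal proteins (adjusted p = 1), S phase genes (1) and matrix genes (0.924) ended. With a drift each list but the clock repressors did. In total RNA and footprints together, 587 genes passed in both (180.7 expected if independent). Their median ratio of footprint to RNA amplitude was 1.24 (quartiles 1.08 and 1.47), 1.22 in the replicate 1 series and 1.24 in the replicate 2 series, and requiring both calls favours genes whose noisier footprint amplitude came out high. Their circular mean phase difference was -0.01 h, with 559 genes (95.2%) within 2 h.

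CKS2, which binds the mitotic kinase CDK1, had the lowest adjusted p of the named genes in knockdown total RNA (0.23 ± 0.02, CT 9.2, adjusted p = 5.65e-08), followed by the mitotic cyclins CCNB1 (0.35 ± 0.03, CT 9.2, 1.16e-07) and CCNB2 (0.32 ± 0.03, CT 10, 7.29e-07). CCNE2, the cyclin of S phase entry, peaked at CT 2.9 (0.50 ± 0.06), FEN1 at CT 5.4 (0.38 ± 0.05) and HIST1H1C at CT 4.9 (0.46 ± 0.06). WEE1 (0.26 ± 0.03), NR1D2 (0.21 ± 0.04, adjusted p = 0.000439), BHLHE40 (0.31 ± 0.06), BHLHE41 (0.43 ± 0.11), ARNTL2 (0.22 ± 0.03), PER2 (0.14 ± 0.04, CT 15.5, 0.0242), CLOCK (0.0289) and DBP (0.0345) passed. ARNTL (0.06 ± 0.06, 0.728), PER3 (0.731), CRY2 (0.823), CRY1 (0.0506), NFIL3 (0.499), TEF (0.0957) and PER1 (0.189) did not. The potassium channel KCNA1 (0.89 ± 0.10), ESM1 (0.89 ± 0.28), SEPP1 (0.89 ± 0.22), DRD1 (0.87 ± 0.18), the early response gene EGR1 (0.79 ± 0.21) and the chemokine CCL2 (0.71 ± 0.14) had large amplitudes. EGR1 was 2.03 and 3.23 (log2) above its group in the 2 shallow libraries. Without them its amplitude was 0.49, and ESM1 (adjusted p = 0.0768), DBP (0.0635) and BHLHE41 (0.0514) were not past the threshold. In all, 4323 of 12765 genes passed, 588 with a linear drift, and 1173 without replicate 1 or 1953 without replicate 2. Total RNA rhythms of both treatments shared 1422 genes (965.7 by independence).

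Among lists in knockdown total RNA, 28 of 29 G2 and M phase genes passed (28 adjusted over the list alone, mean peak CT 8.4, Fisher's exact adjusted p = 2.64e-11), and 28 with a drift (1.17e-35). S phase genes had 25 of 26 (26 over the list alone, 3.09e-10), histones 12 of 12 (1.18e-05), matrix genes 12 of 19 (0.0379, with THBS1 at 0.43 ± 0.05), heat shock genes 10 of 13 (0.00691) and proteasome subunits 19 of 31 (0.00691). Without the 2 shallow libraries matrix, heat shock and proteasome genes did not pass (adjusted p = 0.15, 0.13 and 0.13). With a drift histones (1), matrix genes (1), proteasome subunits (1) and cytosolic ribosomal proteins (0.215) did not, and S phase genes had 6 of 26 (0.00968). Cytosolic ribosomal proteins had 6 of 77, fewer than the 26.08 expected (6.58e-07), and clock repressors 6 of 14 (0.86). In knockdown footprints 1932 of 10635 genes passed, 460 without replicate 1 and 795 without replicate 2. The mitotic genes NEK2 (0.48 ± 0.06, CT 9.1, adjusted p = 5.01e-06), KIF20A (0.47 ± 0.06) and CCNB1 (0.36 ± 0.05) were among them, as were SYT12 (1.13 ± 0.24), ESM1 (1.03 ± 0.29) and CCL2 (0.72 ± 0.15). WEE1 (0.33 ± 0.05) and BHLHE40 (0.23 ± 0.05) passed, but PER2 (0.0825), NR1D2 (0.166), CRY2 (0.246), PER3 (0.699), NR1D1 (0.767) and CRY1 (0.916) did not. G2 and M phase genes had 29 of 29 (5.56e-21; 29 with a drift), S phase genes 24 of 25 (3.07e-16), histones 12 of 12 (8.37e-09), matrix genes 11 of 19 (0.000621), ATF4 targets 12 of 27 (0.0058, with SLC7A5 at 0.26 ± 0.04) and hypoxia genes 9 of 22 (0.0309), while respiratory chain subunits had 5 of 74, fewer than expected (0.0307). Without replicate 1 the calls of histones (adjusted p = 0.749), matrix genes (0.186), ATF4 targets (0.273), hypoxia genes (0.889) and respiratory chain subunits (0.222) ended in footprints. With a drift only G2 and M phase genes passed there. Total RNA and footprints shared 1504 genes (712.9 by independence), with a median amplitude ratio of 1.12 and 87.8% within 2 h.

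**Figure D3:**
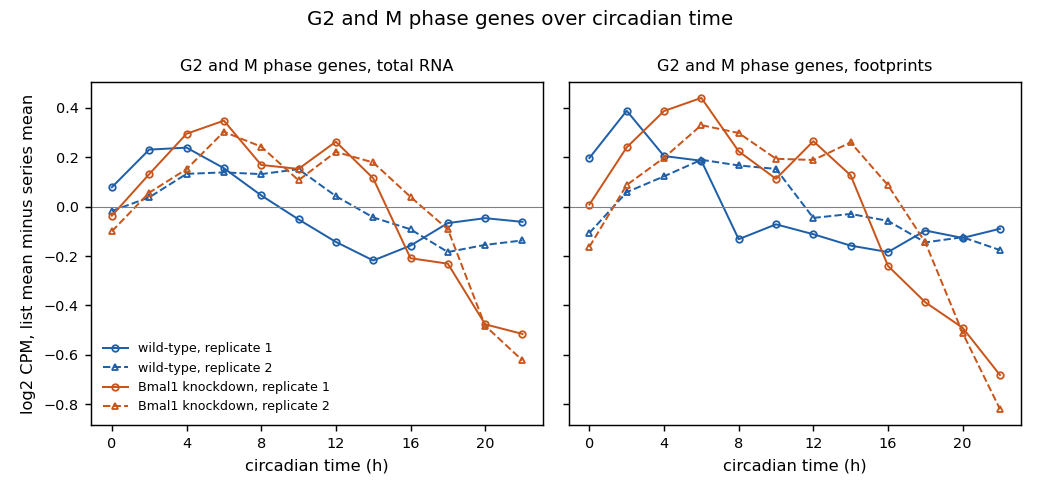
Mean log2 CPM of 29 G2 and M phase genes minus the mean of each series (y axis) over circadian time (h, x axis) in total RNA and footprints; each line is 1 replicate series of wild-type or knockdown cells. The fitted amplitude in total RNA is 0.34 in knockdown and 0.16 in wild-type cells.

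The change of rhythm with knockdown was tested directly, as the length of the difference between the fitted waves. In total RNA it was 0.69 ± 0.07 for ARNTL (adjusted p = 8.32e-08), 0.34 ± 0.04 for CRY1 (8.32e-08), 0.79 ± 0.09 for PER2 (3.25e-07), 0.59 ± 0.08 for PER3 (1.44e-05) and 0.39 ± 0.05 for CRY2 (2.04e-05). TEF (0.61 ± 0.10), NFIL3 (0.30 ± 0.05), NR1D2 (0.30 ± 0.05, 0.00027), RORA (0.33 ± 0.07), PER1 (0.35 ± 0.08), WEE1 (0.18 ± 0.04) and BHLHE40 (0.29 ± 0.08, 0.0301, or 0.0844 without the 2 shallow libraries) also changed. NR1D1 (0.96 ± 0.20) and HLF (0.54 ± 0.14) did at low abundance. HLF averaged only 0.739 CPM in wild-type and 0.631 CPM in knockdown cells, so its value is uncertain. CLOCK (0.0509), DBP (0.339), BHLHE41 (0.549), ARNTL2 (0.383) and NPAS2 (0.727) were not past the threshold. In footprints PER3 (0.52 ± 0.10, 0.0032), PER2 (0.79 ± 0.15, 0.0057), NR1D1 (0.71 ± 0.13, 0.0028, uncertain), CRY1 (0.29 ± 0.06, 0.00499), CRY2 (0.38 ± 0.09), TEF (0.58 ± 0.12), WEE1 (0.28 ± 0.07) and NFIL3 (0.26 ± 0.07, 0.0459) passed. ARNTL (0.85 ± 0.23, 0.0552), with 0 to 6 reads per knockdown library, and NR1D2 (0.28 ± 0.10, 0.19) did not. The counts were 1433 of 13188 genes in total RNA and 431 of 11189 in footprints. Leaving out CT02, CT06 or CT20 gave 951, 847 or 902 in total RNA. In footprints leaving out CT04, CT06, CT16, CT18 or CT20 gave 205, 242, 282, 267 or 147. Without replicate 1 or 2 the counts were 404 or 961 in total RNA and 86 or 135 in footprints.

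The early response gene FOS (0.86 ± 0.19) and DIO2 (0.80 ± 0.14) were among the larger changes of rhythm in total RNA outside the clock lists. EGR1 (0.99 ± 0.28, adjusted p = 0.0408) was not past the threshold without the 2 shallow libraries (0.066), where it stands far above its group. Mitotic genes changed too, with CDK1 at 0.41 ± 0.07 and NEK2 at 0.40 ± 0.06, and 27 of 29 G2 and M phase genes passed (3.15 expected, 28 adjusted over the list alone, Fisher's exact adjusted p = 5.18e-23). So did 12 of 12 histones (2.73e-11), 13 of 16 clock repressors (14 over the list alone, 8.01e-10), 14 of 26 S phase genes (18 over the list alone, 4.31e-07) and 5 of 13 heat shock genes (7 over the list alone, 0.0275, with HSPA8 at 0.19 ± 0.03), a call that ended under each of the 6 alternatives run for it (0.0689 to 0.699). ATF4 targets (4 of 28, 0.808) passed with the replicate block (9 of 28, 0.0416). Cytosolic ribosomal proteins had 0 of 78 in limma (5 at an unadjusted p under 0.05, and 0 in edgeR), fewer than expected (0.000772), and mitochondrial ribosomal proteins 1 of 71 (0.0213). In footprints cytosolic ribosomal proteins had 22 of 66 (41 over the list alone, 1.15e-14), with RPL29 at 0.31 ± 0.06 and RPL3 at 0.23 ± 0.05, and other TOP mRNAs 5 of 17 (13 over the list alone, 0.00116), with the elongation factor EEF2 at 0.19 ± 0.04. G2 and M phase genes had 19 of 29 (29 over the list alone, 2.56e-19) with MKI67 at 0.42 ± 0.08, histones 12 of 12 (9.2e-17), S phase genes 12 of 26 (19 over the list alone, 2.71e-10) and clock repressors 8 of 14 (11 over the list alone, 4.45e-08). All these list p-values take genes as independent, while members of a list can change together. Without replicate 1 the changes of G2 and M phase genes (adjusted p = 0.203 in total RNA, 0.0829 in footprints), histones (0.203 and 1) and S phase genes (0.203 and 1; 0.307 in total RNA without replicate 2) were not past the threshold, nor were clock repressors in footprints (0.293). The low counts of cytosolic (0.469) and mitochondrial ribosomal proteins (0.658) in total RNA were not either. Other TOP mRNAs in footprints were not past it without replicate 2 (0.415). With a drift G2 and M phase genes and clock repressors passed in both assays. Histones (0.496 and 1), S phase genes (0.257 and 0.734; 0.000223 in total RNA with the replicate block too), both ribosomal protein lists in total RNA (1 each), and cytosolic ribosomal proteins and other TOP mRNAs in footprints (1 each) did not. XKR5 (0.90 ± 0.19), GABRA2 (0.88 ± 0.17), KRT34 (0.87 ± 0.17) and SP8 (0.82 ± 0.20) led the changes in footprints.

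Translational efficiency in wild-type cells passed the 24-h test for 8 of 10693 genes (335 at an unadjusted p under 0.05), and for 57 with the replicate block and 1 with the lysate block. Among them were vimentin VIM (0.17 ± 0.03, CT 4.3, adjusted p = 0.00833), RPL28 (0.33 ± 0.06, CT 5.3, 0.00833), the ribosome scaffold GNB2L1 (0.24 ± 0.04, 0.0224), RPS23, RPL37A and RPLP0 (0.21, 0.29 and 0.24, each 0.0429) and the initiation factor EIF3L (0.25 ± 0.05, 0.0465). These are TOP mRNAs, whose 5' end tract of pyrimidines ties their translation to mTOR signalling. No clock gene passed (each adjusted p = 1). The lists held 5 of 66 cytosolic ribosomal proteins (48 adjusted over the list alone, Fisher's exact adjusted p = 8.48e-09; 31 with the replicate block) and 3 of 17 other TOP mRNAs (14 over the list alone, 1.86e-06; 12 with the block), calls that ended with a drift or without replicate 2 (adjusted p = 1 each). DESeq2 gave 22 genes and edgeR 10. The count in limma was 23 without replicate 1 and 0 without replicate 2 (364 unadjusted), 15 without CT00, 5 without CT22, 4 without CT06, 3 without CT12, 2 without CT10 and 0 without CT04, CT14, CT16, CT18 or CT20 (285 to 329 unadjusted), and 32 single libraries moved it by over 1.5 times. In knockdown cells 1 of 10612 genes passed (620 unadjusted). It was the proteasome and BRCA2 partner SHFM1 (0.29 ± 0.05, CT 11.9, 0.0166), named after its values were seen, and it was lost without either replicate, without CT00, CT04, CT10, CT16 or CT22 and without some of 10 single libraries that moved the count; edgeR gave 2 genes and DESeq2 4. The lowest adjusted p of a clock gene was 0.832 (CLOCK). No list held the called gene, so none could pass Fisher's exact test. Fitted to list means instead, knockdown rhythms passed for G2 and M phase genes (0.071 ± 0.02) and heat shock genes (0.059 ± 0.018). With times permuted within series, their permutation adjusted p were 0.02 and 0.0346 over 120 fits. In wild-type cells these fits passed for cytosolic ribosomal proteins (0.185 ± 0.036, CT 4.8, permutation adjusted p = 0.00253) and other TOP mRNAs (0.204 ± 0.034, CT 4.7, 0.0017). Respiratory chain subunits also passed (0.026 ± 0.007, CT 10.5, 0.0144). A steady trend also gives peaks near CT 5.

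The efficiency of TOP mRNAs fell from CT00 to CT22 in wild-type cells as a trend, with ribosomal proteins again uncertain as a family. Cytosolic ribosomal proteins fell by 0.52 ± 0.04 (log2 ± SE, 66 genes, 63 falling in both series and 0 rising in both) and other TOP mRNAs by 0.56 ± 0.03 (17 of 17 falling). In knockdown cells the fitted changes were 0.02 ± 0.07 and -0.03 ± 0.07 (observed CT22 minus CT00 -0.13 and -0.11), and ribosomal proteins went from 0.09 to -0.20 in series 1 and from -0.02 to 0.02 in series 2. The fitted changes differed between the treatments (permutation adjusted p = 7.2e-05 and 4e-05 over 12 tests, with 12 times in each of 2 series). These permutations exchanged single libraries within each time and, like the SEs, took libraries of a series as independent. Exchanging whole series gives only 3 splits, too few for a p under 0.05. The p-values therefore exclude only random assignment of single libraries. For ribosomal proteins in wild-type cells, total RNA rose by 0.15 ± 0.02 (54 of 66 in both series) and footprints fell by 0.38 ± 0.04. The efficiency of mitochondrial ribosomal proteins (-0.01 ± 0.02) and respiratory chain subunits (0.01 ± 0.02) had a fitted linear change smaller than its SE. The mean of the respiratory chain still fitted a small wave (0.026 ± 0.007, peak CT 10.5). Over both TOP lists (83 genes) the change was -0.53 ± 0.04, a fold of 0.694, and -0.53 to -0.59 over 4 scalings, with -0.01 to 0.03 in knockdown cells.

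**Figure D4:**
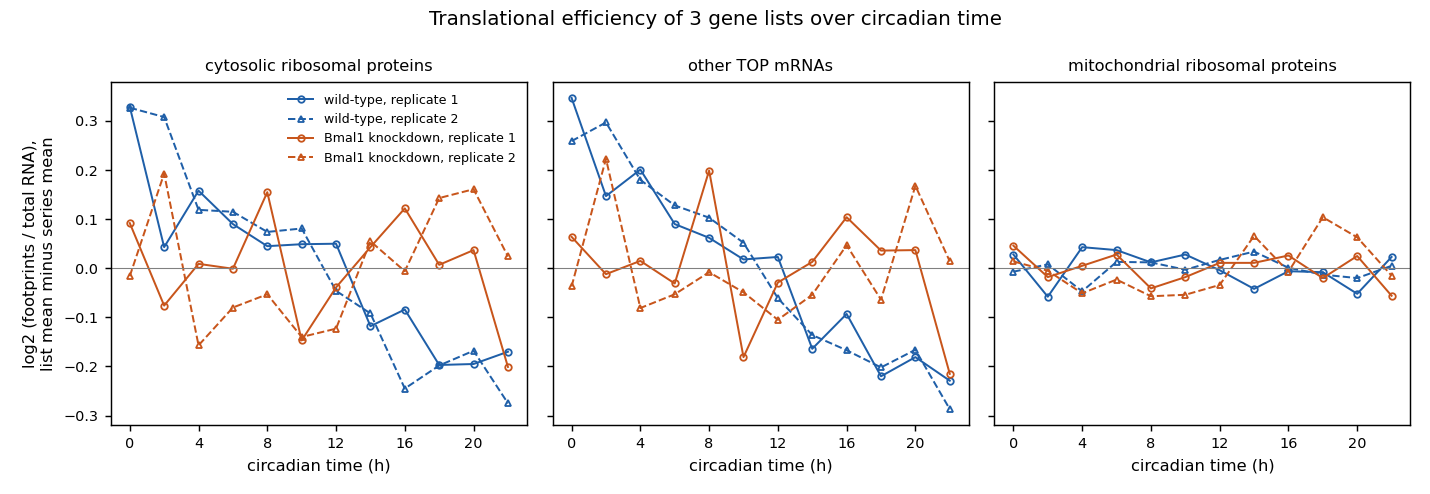
Mean log2 ratio of footprints to total RNA minus the mean of each series (y axis) over circadian time (h, x axis) for cytosolic ribosomal proteins, other TOP mRNAs and mitochondrial ribosomal proteins; each line is 1 of 2 replicate series of wild-type (blue) or knockdown (orange) cells. Both wild-type lines of the TOP lists fall, by a fitted 0.52 and 0.56 from CT00 to CT22, and knockdown lines change by 0.02 and -0.03; over both lists together the wild-type change is -0.53 to -0.59 over 4 scalings.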

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

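The regroupings of samples and the tests of scaling, of seeding or transfection, of wild-type libraries under a knockdown label and of a 24-h cosine were chosen after the results were seen.

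The knockdown effect differed between footprints and total RNA for 3465 genes, a difference between assays tested as an interaction, with SPTAN1 and RPL38 among them. The 24-h rhythm differed between the treatments for 1433 genes in total RNA and 431 in footprints, among them PER2, PER3 and CRY1 in both assays. By list these were 27 of 29 G2 and M phase genes and 12 of 12 histones in total RNA, and 22 of 66 cytosolic ribosomal proteins in footprints. These differences between treatments include seeding density and transfection, and values of histones and ribosomal proteins are uncertain because these families have near-identical members. Without replicate 1 the G2 and M phase list (adjusted p = 0.203) and histones (0.203) were not past the threshold in total RNA, and with a drift histones (0.496) and footprints of ribosomal proteins (1) were not.

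Regroupings of single libraries, 100 for each count with the real grouping included, tested whether samples assigned at random give as many genes. For rhythms within a treatment only a random order of times was excluded. With times exchanged within series, the real and highest other counts were 2855 and 0 (wild-type total RNA, limma), 753 and 1 (wild-type footprints), 4323 and 1518 (knockdown total RNA) and 1932 and 601 (knockdown footprints). In each case only the real one of 100 groupings reached its count. Such exchanges break up a steady drift as well as a rhythm, so they cannot tell a rhythm from a drift. For the rhythm of efficiency in wild-type cells 2 of 100 groupings, the real one among them, reached the real count, 8 genes against 15 at most in another. The count therefore does not stand clear of the regroupings, and 1 gene passed with the lysate block. In knockdown cells the counts were 1 and 0, and a single gene that is lost without either replicate says nothing. With treatments exchanged within times, only the real one of 100 groupings reached its count: 10778 and 5745 genes for total RNA, 8444 and 3178 for footprints, 3465 and 1 for efficiency, and for the change of rhythm 1433 and 33 in total RNA and 431 and 1 in footprints. These exchanges treat libraries as independent, while those of a wild-type total RNA series share deviations (66 pairs, 0.41 to 0.70), so they exclude only random assignment of single libraries. Exchanging whole series gives only 3 splits, too few for a share under 0.05; the real and highest other counts were 10778 and 98 for total RNA, 8444 and 4 for footprints and 3465 and 5 for efficiency.

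S phase, G2 and M phase and histone genes were lower and p53 targets higher in knockdown cells, though with an estimated correlation no such list passed in total RNA (adjusted p = 0.0729 for S phase genes and p53 targets, 0.349 for the others). Scaling of the libraries as the whole cause is argued against by the gap of 1.95 log2 units between the medians of p53 targets and S phase genes in total RNA, since a factor per library moves all genes alike; for that reason other scalings leave such a gap in place and add no evidence. Seeding density, transfection and cleavage of other mRNAs by the siRNAs stay open and cannot be told apart from the loss of BMAL1, because 0 libraries come from untransfected cells at the knockdown's density or from a control siRNA. Loss of BMAL1 itself could also lower proliferation, which was not tested apart from these.

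The knockdown total RNA libraries CT14 and CT18 of replicate 2 deviated together from their group (correlation 0.71 across 10478 genes), with 137 and 175 genes over 2-fold higher, against at most 18 over 2-fold away in any other knockdown total RNA library. NFIC (2.51 and 2.68), SRRM2 (2.10 and 2.17) and EGR1 (2.03 and 3.23) were among those higher. Lower depth is argued against by other libraries thinned to the same depth, whose deviations correlated at 0.40 at most; footprints under a total RNA label by a correlation with the total RNA profile of at least 0.973, against 0.777 and 0.783 with the footprint profile; and wild-type libraries under a knockdown label by ARNTL of at most 6.49 CPM, against 14.3 CPM in the lowest wild-type library. A difference in how these libraries were made may remain, and no biological explanation was tested.

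The ratio of footprints to total RNA of ribosomal protein and other TOP mRNAs fell with time in wild-type cells. Sequencing depth is argued against by a change of -0.55 after thinning every library to the smallest depth of its assay, high abundance by a percentile of 0 among 10000 random lists of like level (their lowest 2.5 percentile was -0.01), short coding sequences by a change of -0.002 in 145 genes of mitochondrial ribosomal proteins and the respiratory chain, and a 24-h cosine by an observed CT22 minus CT00 of -0.55 ± 0.06 where the cosine gives -0.10. A trend with time in culture and a slow output of the clock both stay open, and neither was tested. Density at collection could differ between the treatments, so the lack of a detected trend in knockdown cells (0.02 ± 0.07 for ribosomal proteins, with series that went apart) does not tie the fall to BMAL1.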

How the results depend on the processing

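The alternatives added after the data were seen are edgeR on recovered reads, the deposited scaling, other pseudocounts, library weights, the series means, the leave-out of single libraries and of the 2 shallow libraries, the blocks combined with a drift or time factor and, for lists, camera on voom values, other scalings and the replicate block among rhythmic genes. Over all alternatives, 15159 of 16661 values of named genes kept their side of the threshold and direction, 1434 lost their call, 67 gained 1 and 1 reversed; of 1406 list values 1225 kept theirs, 123 lost it, 51 gained 1 and 7 reversed; and 486 of 642 gene counts stayed within 1.5 times. Knockdown counts moved with a fold threshold of 0.5 (3345 in total RNA, 3010 in footprints, 286 in efficiency) and, for efficiency, with series means, 2 against 2 (878), and a threshold of 0.01 (2269). Counts of rhythms follow in the order wild-type total RNA and footprints, knockdown total RNA and footprints, change in total RNA and footprints. They were 1291, 236, 2500, 1011, 563 and 114 at a threshold of 0.01; 352, 232, 648, 496, 378 and 256 with a peak-to-trough fold of at least 1.5; 25, 7, 588, 262, 154 and 68 with a linear drift; 135, 14, 639, 260, 192 and 84 with a linear drift and replicate block; and 0 in all 6 with a period of 12 h (318 to 762 at an unadjusted p under 0.05 in limma; no other tool was run at this period). With a 12-level time factor, which spends more degrees of freedom, they were 735 and 135 in wild-type total RNA and footprints, 2428 in knockdown total RNA, and 410 and 122 for the change; with the replicate block too, 2703, 766 and 181 in knockdown total RNA and for the change. Library weights gave 1335 in wild-type footprints and 3168 and 736 for the change. Efficiency rhythms in wild-type cells numbered 22 with DESeq2, 13 with TMM over both assays, 15 with the deposited scaling, 30 with library weights, 3 without a filter, 2 at a threshold of 0.01, 1 with a fold of at least 1.5, 57 with the replicate block, 1 with the lysate block, 48 with a time factor and replicate block, and 0 with a linear drift, with or without the block, a time factor or a period of 12 h (160 to 528 at an unadjusted p under 0.05 in limma, against 335; no other tool was run with these terms). In knockdown cells they numbered 4 with DESeq2, 2 with edgeR, 3 with library weights, 3 without the 2 shallow libraries, 5 with the lysate block, and 0 at a threshold of 0.01, a time factor, a fold of at least 1.5 or a period of 12 h (200 to 620 at an unadjusted p under 0.05 in limma). The replicate block, where replicate numbers pair the libraries, raised wild-type total RNA to 4830; in wild-type footprints, where libraries share only a number (66 pairs, -0.06 to 0.45), it gave 1337. Pairs of knockdown and wild-type libraries correlated at -0.17 to 0.18 in total RNA and -0.05 to 0.22 in footprints, total RNA and footprints of knockdown cells at -0.02 to 0.48, and times at -0.21 to 0.60 and -0.19 to 0.17 in knockdown total RNA and footprints, so numbers did not pair these. With the block the knockdown counts were 10917, 8508 and 3776 in total RNA, footprints and efficiency (4165 with the lysate block), and it moved no other count of genes by over 1.5 times. Lists past the threshold under knockdown numbered 0 of 9 in total RNA, 2 of 6 in footprints and 0 of 5 in efficiency with an estimated correlation, and 18, 15 and 11 with fry, which asks a different question. Lists among rhythmic genes numbered 1, 1, 4, 1, 2 and 2 with a linear drift (against 5, 7, 7, 7, 7 and 6; the 4 include p53 targets, which did not pass without it) and 2, 1, 4, 1, 3 and 2 with the block added, 0 for wild-type efficiency in both, 8 in wild-type total RNA with the replicate block, and 4 in knockdown total RNA without the 2 shallow libraries. The cytosolic ribosomal protein list in wild-type total RNA reversed with the block, from fewer than expected, not past the threshold, to more (adjusted p = 1.11e-05). Leaving out a replicate, time or library gave these ranges: efficiency under knockdown 1871 to 3318; rhythms 1619 to 3098, 140 to 879, 1173 to 4610, 460 to 2092, 404 to 1826 and 86 to 551; efficiency rhythms 0 to 23 and 0 to 2; lists 3 to 6 for efficiency under knockdown, 5 to 12, 3 to 9, 3 to 5, 3 to 5 and 3 to 6 for wild-type total RNA and footprints, knockdown footprints and the changes, and 0 to 2 for wild-type efficiency. Some lists that were not past the threshold with all libraries passed it in the opposite direction with a replicate left out, with adjusted p over the 2 replicates of 2.1e-06 to 0.286 for cytosolic ribosomal proteins, 8.93e-08 to 0.621 for histones and 0.00249 to 0.191 for cholesterol genes in wild-type total RNA, 2.28e-05 to 1 for histones in wild-type footprints, 0.00073 to 0.692 for cytosolic ribosomal proteins in knockdown footprints and 0.00842 to 0.318 for matrix genes in the change in footprints. NPAS2 in footprints was -0.01 without replicate 1 (adjusted p = 0.946) and 0.45 without replicate 2. The cause of these changes was not tested. With replicates left out the knockdown tests used an additive model. On data simulated at the real depths, 26.9% of efficiency rhythms with an amplitude of 0.25 were recovered in wild-type cells; depth was not varied for these calls, so what it limits apart from the spread between replicates was not measured.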

Other observations

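The test of the G2 and M phase wave was chosen after the result was seen. The wave of 29 G2 and M phase mRNAs may be stronger in knockdown than in wild-type cells. The amplitude of the list mean was 0.34 in knockdown and 0.16 in wild-type total RNA (permutation p = 0.0018), and 0.41 and 0.16 in footprints (permutation p = 0.00067). By series the amplitudes in total RNA were 0.355 and 0.328 in knockdown and 0.192 and 0.164 in wild-type cells. The wild-type series peaked apart, at CT 3.3 and 7.1, which lowers the amplitude of their mean. The permutation did not exchange whole series, 2 per treatment, so it takes libraries as independent. Without replicate 1 the list's change of rhythm was not past the threshold (Fisher's exact adjusted p = 0.203 in total RNA, 0.0829 in footprints). A partial synchrony of the cell cycle after sparser seeding could give the same difference in amplitude, and no library separates it from the loss of BMAL1.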
